A study of Danio rerio with 36 samples.

How the data were processed

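The series measured gene expression in whole zebrafish embryos with 2-colour arrays of spotted oligonucleotides. Per the labels' protocols, groups of 30 fertilised eggs were exposed in 15 ml of test solution at 26 °C in 80 mm dishes from about 1.5 h after fertilisation, and sampled at 72 h after fertilisation. Amplification started from 0.35 µg total RNA per extract and gave aminoallyl RNA, which was coupled to Cy3 or Cy5. Each of 4 toxicants (3,4-dichloroaniline, DCA; 2,4-dichlorophenol, DCP; pentachlorophenol, PCP; cadmium chloride, CdCl2) was given at a low and a high concentration beside its own unexposed control, which makes 12 conditions of 6 channels each on 36 arrays. The arrays form an interwoven loop: 24 compared conditions of the same toxicant, with 2 arrays of opposite dye orientation for each pair, and 12 linked toxicants at the same level of exposure. Groups and replicate numbers were taken from the sample titles. PCP control replicate 3 is named on 2 arrays, both times in Cy3, so the 6 PCP control channels stand for 5 labelled samples. Both channels were kept in the fit. Across probes they correlated at 0.886, and other pairs of PCP control channels at 0.735 to 0.914. No 2 channels held identical values.

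The deposited scanner files hold, per the file headers, spot intensity in each channel as BlueFuse for Microarrays 3.4 quantified it, with no column of background, so the amplitudes were taken as already corrected. They also hold, per the file headers, the software's estimate, as a fraction from 0 to 1, that a spot is present in a channel. No spot was marked as excluded on any array. The authors' deposited table of normalized ratios was read as log2 values. Its log base, scale and centring are not given in the sources used here. Its 16383 entries all matched a probe tested here, its column medians lay between -0.053 and 0.035, and across probes each column correlated at 0.51 to 0.93 with the log2 ratio of scanner channel 2 to channel 1 of the same array, with slopes of 0.303 to 1.34. That table served as an alternative only.

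Cy5 was taken to be scanner channel 2. This rests on the order of the samples in the titles and on the positive correlation of the deposited ratios with channel 2 over channel 1, since the headers do not tie a dye to a channel. An exchange of the dyes on all arrays, which would turn the sign of every fold change, was tested after the data were seen. Condition levels were estimated from the average intensity of each array, which the order of the dyes does not enter. Their differences had the sign of the fold change for 83% of the 2918 probes past the threshold in DCA high, 79.5% of the 4194 in CdCl2 high and 86.8% of the 242 in CdCl2 low, where an exchange requires a minority. In DCP high it was 38.6% of 44, and PCP had at most 2 probes to compare. The SD of the probe for AW342687 within a condition was 0.496 for DCA low and 0.527 for DCA controls, and would be 3.59 and 4.25 with the dyes exchanged. Among the 12 conditions it would be lower with the dyes exchanged only in DCP controls (1.585 against 1.605) and CdCl2 low (0.857 against 0.966). The values thus argue against such an exchange; single arrays were not tested.

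Each array carried 17328 spots in 48 print blocks, of which 750 were control spots and 172 repeated a single sequence. These were left out of the tests and given weight 0 in the normalization, leaving 16406 probes. The log2 ratio of each array was normalized by loess against intensity. A model with a coefficient for each condition and an intercept for the dye was fitted to all 36 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 24 residual and 1.71 prior degrees of freedom. Probes passed at a Benjamini-Hochberg adjusted p under 0.05. Differences among the 4 control groups and among the 4 responses were tested with limma's moderated F. Levels per condition are log2 intensities of separate channels after quantile scaling of the average intensities, as mean and SD over 6 channels. The folds come from the fit over the loop, which also uses the linking arrays, and so can differ from the difference of these means.

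The median amplitude per array ran from 172.4 to 949.5 in Cy5 and from 297.3 to 1500 in Cy3, and the tested probes were present (fraction of at least 0.5) in 72.8% of channels, against 7.79% for empty spots. The number of arrays limits the precision. The replicates are separate dishes of a single exposure day per toxicant, so p-values measure the spread between dishes and arrays, and toxicant and exposure day cannot be separated. Arrays were scanned on 8 days, and scan day was tested as a batch, with a dye intercept for each day. Fits within a scan day had 2 or 3 residual degrees of freedom, so a count of 0 there does not show that values did not differ. On the scan day that held the PCP arrays, DCA and CdCl2 had at most 1 channel per condition, so their fits there set 1 sample against 1.

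Probes carry sequence accessions. Through the RefSeq gene table of assembly GRCz12tu, with versions removed, 48 probes of 47 genes received a symbol, out of 16326 accessions; 13 further RefSeq accessions were not in the table. Before the data were examined, 33 gene lists were fixed for the toxicants and tissues. Of these, 29 had no named member on the array, 3 had 1 or 2 (AhR and phase 1: cyp2ad2; immediate early: egr1 and egr2b; liver: cyp2ad2 and rbp4) and the thyroid list had 3. After the data were opened and a first quick fit had shown its leading probes, 9 groups were made from the names of the 47 genes alone, before the values of those genes were seen. A set of 13 probes that share the accession of 1 RefSeq molecule was added. Whether these probe a single transcript was not determined. Lists and groups were tested with camera, with a preset correlation of 0.01 and with an estimated one. The metallothionein gene mt2 and cyp1a, which were to be given in every comparison, were not among the named probes. Where 2 probes shared an accession (29 accessions), their log2 fold changes correlated across accessions at -0.015 for DCA high and 0.149 for CdCl2 high. Over all exposures against control, r lay between -0.295 (PCP low) and 0.149. Such probes thus did not move together, and the level of 1 probe may not stand for its gene.

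The genes named here follow a rule fixed before the data were examined. For each toxicant it takes the named genes past the threshold with the same sign on both direct arrays, up to 10 higher and 10 lower for the high concentration, 5 and 5 for the low, and 3 and 3 for high against low; where none passes, the 3 of smallest p are given, and up to 4 members are given of a list with a call. For the control groups it takes the 5 largest ranges. Unnamed probes, at most 2 in each direction per comparison, were chosen after their values were seen, as the largest changes among those present in all 6 channels of a group and of the same sign on both direct arrays, or as members of a count of at most 5. A probe was taken as not above background in a group where its presence estimate was under 0.5 in each of the 6 channels; no fold is given where that held in both groups. Where it held in 1 group, the fold is a lower bound: the mean of the other group against the mean of, per channel, the higher of the probe's own level and the lowest level among present probes. No bound under 1 is given. The brightest probe stands for a gene.

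The fit was tested on simulated arrays with the real design and the spread of each of the 16406 probes. Of 50 probes changed by 2 on the log2 scale, 60% were recovered for DCA high against control, 62% for DCP, 50% for PCP and 60% for CdCl2. Of 50 changed by 1, it was 36%, 34%, 16% and 34%. The simulated noise was normal and independent between probes and arrays, which need not hold for the real arrays. Alternatives fixed before the data were examined were print-tip loess, the deposited table, a filter for 13446 probes present in a channel on at least 18 arrays, no dye term, array weights, a trended robust prior, scan day as a batch, separate channels (with statmod 1.5.0), separate channels with the replicate number as a block, the 6 arrays of a toxicant alone, and each array left out in turn. The filter used the software's presence estimate in place of the background columns it was written for. The planned comparisons of background corrections and of excluded spots had nothing to act on. Chosen after seeing the data were an offset of 50, the loss of spots of the lowest confidence class, the loss of an array that stood apart and the loss of 5 arrays of low weight. That class held 31.3% to 48.3% of the tested spots of an array (median 43.15%), all kept in the main fit.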

Results

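The arrays held RNA of whole zebrafish embryos at 72 h after fertilisation from 12 conditions, 6 channels each on 36 arrays. The labels give 0.473 and 0.946 mM for the low and high concentration of DCA, an aromatic amine with 2 chlorines, and 1.85 and 3.71 mM for DCP, a phenol with 2 chlorines. They give 0.093 and 0.185 mM for PCP, a phenol with 5 chlorines, and 4.7 and 9.3 mM for CdCl2. The unit is as labelled, and no file bears on it. The question of each comparison was how an exposure shifted transcript levels against unexposed embryos of the same exposure day. Log2 fold changes are given with their SE, as exposed over control. Cy5 is taken as scanner channel 2, and levels compared between arrays argued against an exchange of the dyes. Named genes are few, 47 on an array of 16406 tested probes. Those with a call carry probe numbers of the same source plate.

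**Figure D1:**
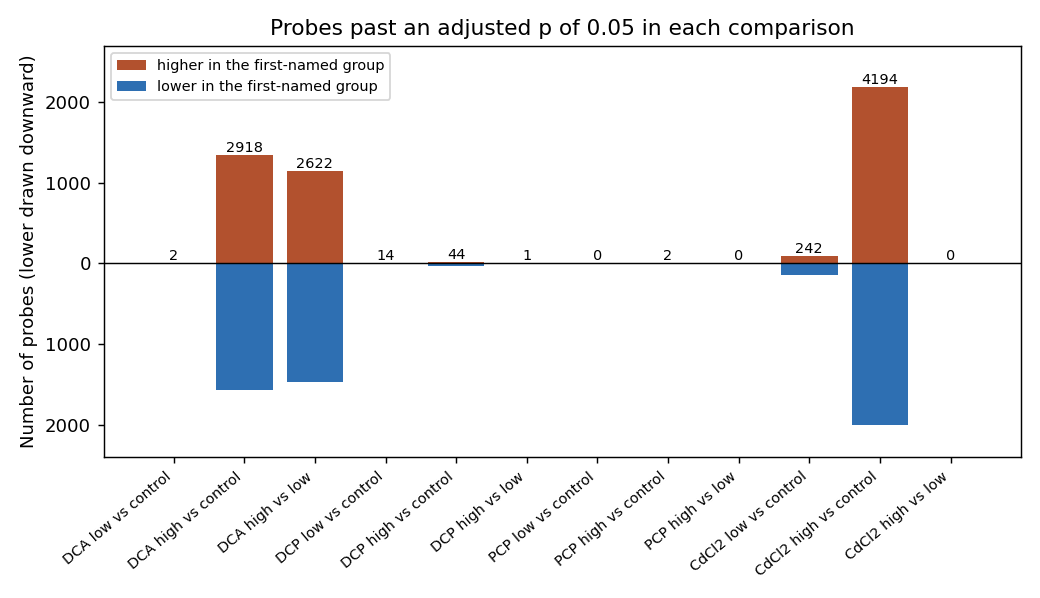
Number of probes past an adjusted p of 0.05 in each of the 12 comparisons within a toxicant, with higher probes drawn upward, lower probes drawn downward and the total above each bar. The largest bars are CdCl2 high against control with 4194 probes and DCA high against control with 2918.

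In embryos exposed to the low concentration of DCA, 1 probe stood far above all others. The unnamed probe for AW342687 was 95.8-fold higher than in DCA controls (log2 fold change 6.58, SE 0.38, adjusted p = 2.34e-11), at a log2 intensity of 14.78 ± 0.50 (SD, n = 6) against 8.62 ± 0.53 (SD, n = 6). Its ratio was 6.83 and 6.09 on the log2 scale on the direct arrays of opposite dye orientation. No named gene passed. Those of smallest p were wt1a at 0.55 (SE 0.31), hoxb6a at 1.63 (SE 0.94) and sox21a at -2.08 (SE 1.25), each with an adjusted p of 1. The channel means of wt1a went the other way, 7.68 against 7.84. In all, 2 of 16406 probes passed, 1 higher and 1 lower, and 516 had an unadjusted p under 0.05. The lower of these, the unnamed BI886662, singled out after its values were seen, was present in 1 of 6 channels of each group. With scan day as a batch the count was 3, and within scan days it was 1 (3 residual degrees of freedom) and, with 1 channel per group, 0 (442 and 1108 at an unadjusted p under 0.05).

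At the high concentration of DCA, 2918 probes passed, 1350 higher and 1568 lower than in DCA controls. Among named genes, dlx4a, a homeobox transcription factor, fell by 3.16 on the log2 scale (SE 0.79, adjusted p = 0.00842). The gene for the retinol carrier of blood, rbp4, fell by 1.90 (SE 0.59, adjusted p = 0.0276). The muscle growth inhibitor gene mstnb, a myostatin, fell by 1.76 (SE 0.55, adjusted p = 0.0283). Levels also fell for nkx2.1, a transcription factor of the thyroid and ventral forebrain, by 1.37 (SE 0.47, adjusted p = 0.0432), and for mafba, a transcription factor of hindbrain patterning, by 0.48 (SE 0.16, adjusted p = 0.0377). The homeobox gene dlx1a, active in the forebrain, was the named gene that rose, by 0.87 (SE 0.23, adjusted p = 0.01). In the fit, DCA controls were the highest of the 4 control groups for dlx4a, rbp4, mstnb and nkx2.1 and the lowest for dlx1a. For mafba, PCP controls were the highest. By channel means, however, dlx1a was lower in PCP controls (9.37) than in DCA controls (10.05), and mafba was highest in DCA controls (11.82). The probe for AW342687 was 68.6-fold higher (log2 fold change 6.10, SE 0.38, adjusted p = 1.4e-10). Among other unnamed probes, AW567244 rose by 3.00 (SE 0.89), while BI865553 fell by 4.78 (SE 0.95) and BI845755 fell by 4.67 (SE 1.09), with adjusted p from 0.00307 to 0.0206. AW567244 was present in 1 of 6 control channels, and BI865553 and BI845755 in 1 of 6 channels at the high concentration, where mstnb was present in 3 of 6 and dlx4a in 4 of 6. On the direct arrays the log2 ratios were -5.75 and -0.61 for dlx4a, -3.96 and -0.28 for mstnb, and -8.71 and -1.08 for BI865553. For these and every other gene and probe of this paragraph, the larger came from the array of DCA high replicate 1 and DCA control replicate 4. That array had the lowest estimated weight of the 36, 0.333.

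Of the 8 dlx genes measured in DCA high against control, 1 rose and 1 fell, both also when adjusted over the list alone, with a median of 0.17 and a mean of the other sign, -0.26. Of the thyroid list, fixed beforehand, nkx2.1 fell while nkx2.4b (-0.11, SE 0.42) and thrb (-0.25, SE 1.00, present in 1 of 6 channels of each group) did not pass, and the count adjusted over the list alone was also 1. The thyroid list's shift did not pass with camera (adjusted p = 0.786, and adjusted p = 0.794 with an estimated correlation). Of the liver list, rbp4 fell, likewise adjusted over the list alone, and cyp2ad2, the 1 named member of the AhR and phase 1 list, was present in 1 of 6 exposed and 0 of 6 control channels and did not pass (adjusted p = 0.732). Neither egr1 (-0.41, SE 0.19) nor egr2b (-0.06, SE 0.88) of the immediate early list passed. The count of 2918 fell to 1346 without the array of DCA high replicate 1 and DCA control replicate 4, without which none of the 6 named genes, AW567244 or BI845755 passed, and to 1943 without that of DCA control replicate 3 and DCA low replicate 2. In all, the call of nkx2.1 was lost without any of 9 arrays, those of rbp4 and mafba without any of 5 and that of mstnb without either of 2. Over 15 alternatives the call was lost in 2 for dlx4a, 3 for dlx1a, 6 each for rbp4 and nkx2.1 and 7 for mafba, and for mstnb in 5 of 14. The count was 1770 with the deposited table and 1330 without 5 arrays of low weight. It was 2829 with scan day as a batch, and 1 within the scan day of the 6 DCA arrays (2385 at an unadjusted p under 0.05). That fit had 3 residual degrees of freedom, and its fold changes correlated across probes at 0.947 with those of all arrays, of which its own are a part. On the scan day that reached DCA through PCP, with 1 channel per group and 2 residual degrees of freedom, that correlation was 0.449.

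Between the high and low concentration of DCA, 2622 probes differed, 1152 higher and 1470 lower at the high concentration. The homeobox gene dlx1a was higher by 0.75 on the log2 scale (SE 0.23, adjusted p = 0.0259). Lower levels were found for dlx4a, which fell by 2.38 (SE 0.79, adjusted p = 0.0402), for the immediate early transcription factor egr1, which fell by 0.59 (SE 0.19, adjusted p = 0.0343), and for mafba, which fell by 0.48 (SE 0.16, adjusted p = 0.0398). Without the array of DCA low replicate 5 and DCA high replicate 4 the count was 942, without that of DCA high replicate 3 and DCA low replicate 4 it was 1302, and without the arrays linking PCP and DCA it was 1634 (low) or 1727 (high). None of the 4 named genes passed without any 1 of these 4 arrays, and dlx4a and mafba each lost the call without any of 9. Over 15 alternatives the 4 genes lost it in 4 (dlx4a) to 7 (mafba). The count was 1509 with the deposited table, 2400 with scan day as a batch, and 0 within the scan day of the 6 DCA arrays (1810 at an unadjusted p under 0.05). That fit also had 3 residual degrees of freedom, and its fold changes correlated at 0.933 with those of all arrays, of which its own are a part. On the scan day with 1 channel per group and 2 residual degrees of freedom, that correlation was 0.564.

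**Figure D2:**
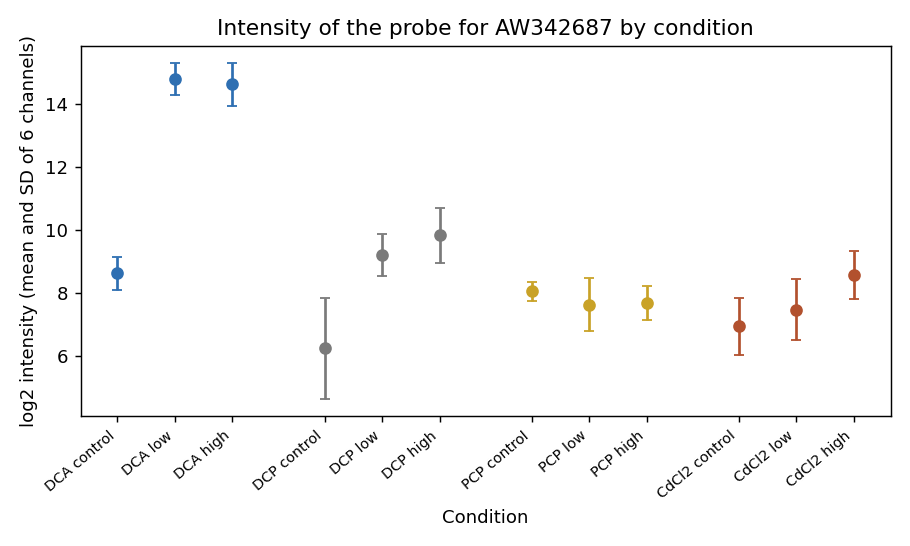
Log2 intensity of the probe for AW342687 in the 12 conditions, as the mean of 6 channels with SD (in PCP controls, 6 channels of 5 labelled samples). The DCA low and high groups sit at 14.78 and 14.61 against 8.62 in DCA controls, and the 3 PCP groups lie between 7.63 and 8.05.

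With DCP, AW342687 was again the leading probe. It was 8.56-fold higher at the low concentration (log2 fold change 3.10, SE 0.38, adjusted p = 0.000277) and 18.6-fold higher at the high concentration (4.22, SE 0.38, adjusted p = 5.51e-07), on both direct arrays each time. Neither call held with the deposited table or with the 6 DCP arrays alone, nor did the low one without spots of the lowest confidence class. The probe was present in 6 of 6 channels of each exposed group and in 1 of 6 channels of DCP controls. At the high concentration AW165158 rose by 1.19 (SE 0.25), BG305996 fell by 1.85 (SE 0.40) and BM026584 fell by 1.62 (SE 0.35), with adjusted p from 0.0406 to 0.0424, and these calls were lost without any of 17, 23 and 16 arrays. No named gene passed at either concentration. At the high concentration mafba was at 0.42 (SE 0.16, adjusted p = 0.181) and hoxa2b at 0.79 (SE 0.31, adjusted p = 0.191), while inhbb (adjusted p = 0.199) was not above background in any channel of either group. At the low concentration gdf6b was at 1.05 (SE 0.39, present in 1 of 6 channels of each group), dlx4a at 2.1 (SE 0.79) and dlx4b at 2.58 (SE 0.98), each with an adjusted p of 0.427. Both members of the immediate early list lay above 0 in the fit at the high concentration, with a median of 0.44 and no call, but their channel means were lower than in controls, 10.99 against 11.09 for egr1 and 6.30 against 6.54 for egr2b.

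In all, 14 probes passed for DCP low against control, 3 higher and 11 lower, and 44 for DCP high against control, 16 higher and 28 lower, with 1770 and 2774 at an unadjusted p under 0.05. Between the concentrations 1 probe passed, the unnamed BE017866, lower at the high one and present in 1 of 6 channels there, and among named genes gdf6b (-1.31, SE 0.39, adjusted p = 0.374), dlx5a (-1.90, SE 0.58, adjusted p = 0.421) and phc2a (-1.57, SE 0.54, adjusted p = 0.545) did not pass. The 44 ranged from 8 to 714 when 1 of the 36 arrays was left out, and 16 arrays moved it by over 1.5 times. The 14 ranged from 3 to 85, moved so by 18 arrays. With scan day as a batch the counts were 17 (58.8% higher in place of 36.4%) and 11. For DCP high it was 215 without spots of the lowest confidence class, 25 (88% higher) without 5 arrays of low weight, 29 without a dye term, 2 with array weights or an offset of 50 and 0 with the deposited table. For DCP low it was 33 with separate channels and 1 with array weights or an offset of 50. Within the scan day of the 6 DCP arrays, with 3 residual degrees of freedom, both were 0 (676 and 492 at an unadjusted p under 0.05), as was the count between the concentrations (602), which was also 0 with scan day as a batch. The count between the concentrations was 0 to 7 with 1 array left out. It was larger with separate channels, with or without the replicate number as a block. DCP high against control also had a larger count with that block.

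With PCP, 1 unnamed probe, BI892352, was lower at the high concentration by a log2 fold change of -1.07 (SE 0.19, adjusted p = 0.0407), at 13.11 ± 0.31 (SD, n = 6) against 13.91 ± 0.57 (SD, n = 5 labelled samples, with the channels of the repeated number averaged) in PCP controls. No named gene passed at either concentration. At the high concentration egr1 was at -0.45 (SE 0.19, adjusted p = 0.609) and tlx2 at -0.47 (SE 0.20, adjusted p = 0.609). For inhbb, present in 1 of 6 exposed and 0 of 6 control channels, the channel means gave a bound of 1.39-fold. Its difference in the fit did not pass (adjusted p = 0.621), so no rise is shown. At the low concentration egr1 was at -0.26 (SE 0.19) and tlx2 at -0.23 (SE 0.20), and spns1 was present in 0 of 6 exposed and 1 of 6 control channels, each with an adjusted p of 1. Between the concentrations inhbb (bound from channel means 1.44-fold, adjusted p in the fit 0.824), mafba (-0.28, SE 0.16) and dlx4b (-1.69, SE 0.98) had the smallest p and did not pass. AW342687 was at 0.23 (SE 0.38) and 0.41 (SE 0.38) in the fit, with adjusted p of 1 and 0.849, while its channel means went the other way, 7.63 and 7.70 against 8.05. With limma, 0 probes passed for PCP low against control and 0 for high against low, with 298 and 963 at an unadjusted p under 0.05. For PCP high against control 2 passed, BI892352 and the unnamed AI883170, which was higher but present in 1 of 6 exposed and 0 of 6 control channels, with 1269 at an unadjusted p under 0.05. That count was 0 without the 2 arrays on which the number of PCP control replicate 3 is repeated, 1 with scan day as a batch, 0 within the scan day of the PCP arrays, with 2 residual degrees of freedom (1097 at an unadjusted p under 0.05), and it moved by over 1.5 times without any of 25 arrays. A much larger count came with the replicate number as a block on separate channels, although the numbers were not taken to pair the samples. A pairing of some samples by these numbers was not excluded, so the small count depends on that choice. The call of BI892352 was lost without any of 26 arrays. For PCP low against control and for high against low, 0 passed within that scan day (716 and 1421 at an unadjusted p under 0.05).

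At the high concentration of cadmium chloride, 10 of the 47 named genes were higher than in CdCl2 controls and 1 was lower. In the fit, CdCl2 controls were the lowest of the 4 control groups for each of the 10, and the highest for the 1. By channel means, DCP controls were lower than CdCl2 controls for rbp4 (10.48 against 10.72) and nkx2.1 (10.51 against 10.72). DCA controls were lower for egr1 (10.51 against 10.79), and DCP controls were higher for dlx1a (10.93 against 10.59). How far the changes after CdCl2 lie in the controls rather than in the exposed embryos cannot be told from these groups. The homeobox genes dlx4a and dlx5a rose by 2.39 (SE 0.79, adjusted p = 0.0265) and 2.37 (SE 0.58, adjusted p = 0.00408) on the log2 scale. The retinol carrier gene rbp4 rose by 2.17 (SE 0.59, adjusted p = 0.00859), mstnb by 1.84 (SE 0.55, adjusted p = 0.0157) and nkx2.1 by 1.74 (SE 0.47, adjusted p = 0.00798). The hindbrain gene hoxa2b rose by 1.42 (SE 0.31, adjusted p = 0.00175), hesx1, a transcriptional repressor needed for forebrain and pituitary development, by 1.36 (SE 0.37, adjusted p = 0.00789) and the neuronal homeobox gene tlx2 by 0.98 (SE 0.20, adjusted p = 0.00135). Smaller rises were found for egr1, 0.59 (SE 0.19, adjusted p = 0.0240), and mafba, 0.57 (SE 0.16, adjusted p = 0.00955). The 1 named gene that fell was dlx1a, by 0.66 in the fit (SE 0.23, adjusted p = 0.0325) and on both direct arrays, although its channel means over all arrays were 10.62 and 10.59. Among unnamed probes BI845755 rose by 3.91 (SE 1.09) and BF717383 by 3.76 (SE 0.77), while BI880958 fell by 3.52 (SE 0.99) and BI880613 fell by 3.07 (SE 0.90), with adjusted p from 0.00126 to 0.0133. At the high concentration BI880958 was present in 3 of 6 and BI880613 in 1 of 6 channels; in CdCl2 controls BF717383 was present in 3 of 6, and dlx4a, dlx5a, mstnb, hesx1 and AW342687 in 4 of 6 each. AW342687 was 6.37-fold higher (log2 fold change 2.67, SE 0.38, adjusted p = 0.000418).

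By group, 2 dlx genes rose and 1 fell of 8 measured (median 1.16), 3 of 8 other homeobox genes rose, namely hesx1, nkx2.1 and tlx2 (median 0.76), and 1 of 7 Hox genes rose (median 1.02). None of these groups passed camera for CdCl2 high against control (adjusted p = 0.518, 0.112 and 0.593, and adjusted p = 0.803 for each with an estimated correlation). Of the thyroid list, nkx2.1 rose, and 2 of its 3 genes rose when adjusted over the list alone; nkx2.4b was at 1.12 (SE 0.42, adjusted p = 0.0509) and thrb at -1.43 (SE 1.00, present in 1 of 6 exposed and 3 of 6 control channels). The list's camera test did not pass (adjusted p = 0.786, and adjusted p = 0.794 with an estimated correlation). Of the immediate early list egr1 rose and egr2b was at -0.06 (SE 0.88), with channel means of 8.14 against 7.94, and of the liver list rbp4 rose while cyp2ad2 was present in 0 of 6 exposed and 1 of 6 control channels (adjusted p = 0.63), with the same counts adjusted over the list alone.

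**Figure D3:**
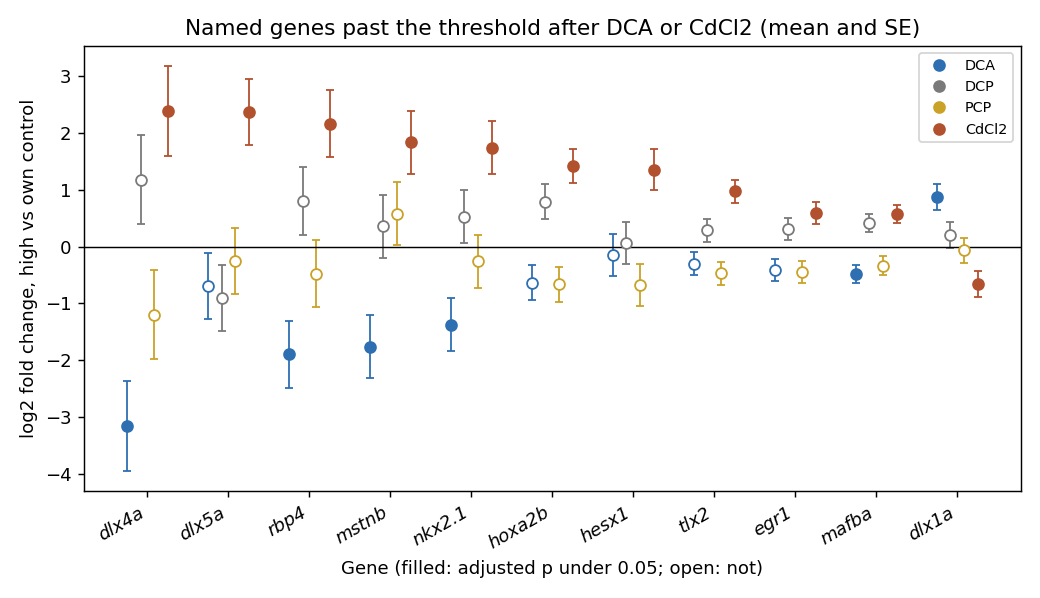
Log2 fold change of the high concentration over its own control with SE for the 11 named genes past the threshold after DCA or CdCl2, in all 4 toxicants; filled points have an adjusted p under 0.05. The genes that pass after DCA lie on the other side of 0 after CdCl2, as for dlx4a at -3.16 and 2.39.

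In all, 4194 probes passed for CdCl2 high against control, 2194 higher and 2000 lower. It was 1565 with the deposited table, 722 (40% higher in place of 52.3%) with scan day as a batch, and 0 within the scan day of 5 CdCl2 arrays (2950 at an unadjusted p under 0.05). That fit had 2 residual degrees of freedom, and its fold changes correlated at 0.832 with those of all arrays, of which its own are a part. On the scan day that reached CdCl2 through PCP, from 1 CdCl2 high channel against 1 control channel and 2 residual degrees of freedom, that correlation was 0.51. The count was 1765 without the array of CdCl2 control replicate 4 and CdCl2 high replicate 3, and 2586 without that of CdCl2 high replicate 2 and CdCl2 control replicate 3. The genes dlx4a, rbp4, nkx2.1, egr1, mafba and dlx1a each lost their call without either, dlx4a in all without any of 5 arrays and dlx1a without any of 6. The call of mstnb was lost without the latter, whereas dlx5a, hoxa2b, hesx1 and tlx2 kept theirs without any 1 of the 36 arrays. Over 15 alternatives, however, the call was lost in 2 for dlx5a (adjusted p up to 0.0582), 1 for hoxa2b (0.0585), 4 for hesx1 (0.133) and 2 for tlx2 (0.083), and in 4 to 9 for dlx4a, rbp4, nkx2.1, egr1, mafba and dlx1a. For mstnb it was lost in 5 of 14. BI845755 lost its call without either, BI880613 without the former and BI880958 without the latter.

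At the low concentration of CdCl2 no named gene passed. Those of smallest p were hoxa2b at 0.99 (SE 0.31, adjusted p = 0.0761), tlx2 at 0.64 (SE 0.20, adjusted p = 0.0812) and mafba at 0.42 (SE 0.16, adjusted p = 0.137). All 8 of the other homeobox genes lay above 0 (median 0.59), a shift that did not pass camera (adjusted p = 0.0703, and adjusted p = 0.803 with an estimated correlation), and 1 of them passed when adjusted over the list alone, as did egr1 of the immediate early list (0.46, SE 0.19). The set of 13 probes that share the accession of 1 RefSeq molecule, not known to be a single transcript, was lower, at a median of -0.34. Of the 13, 0 were higher (camera, adjusted p = 0.00113, but adjusted p = 0.803 with an estimated correlation). The count was 242, 97 higher and 145 lower, with 3097 at an unadjusted p under 0.05. It was 0 with scan day as a batch, without a dye term, with the deposited table, within the scan day of 5 CdCl2 arrays, with 2 residual degrees of freedom (2399 at an unadjusted p under 0.05) and without any of 24 arrays. It was 1722 with array weights, 986 without spots of the lowest confidence class, 659 with a trended robust prior, 557 with an offset of 50 and 523 with the dim probe filter, and at most 880 without 1 array. Between the concentrations 0 probes passed with limma, with 2849 at an unadjusted p under 0.05, and 1904 passed with array weights. The count was 0 within the scan day of 5 CdCl2 arrays, with 2 residual degrees of freedom (2233 at an unadjusted p under 0.05). The named genes of smallest p in that comparison were rbp4 at 2.25 (SE 0.59, adjusted p = 0.166), nkx2.1 at 1.67 (SE 0.47, adjusted p = 0.166) and dlx1a at -0.66 (SE 0.23, adjusted p = 0.171).

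The chlorinated aromatic compounds were compared by the difference of their responses to the high concentration, each against its own controls; the concentrations differed, 0.946 mM for DCA, 3.71 mM for DCP and 0.185 mM for PCP. Between the amine DCA and the phenol DCP, which both carry 2 chlorines at different positions, the response was lower with DCA for dlx4a by a log2 difference of -4.34 (SE 1.04, adjusted p = 0.00403), rbp4 by -2.70 (SE 0.78, adjusted p = 0.0133), mstnb by -2.12 (SE 0.73, adjusted p = 0.0353) and nkx2.1 by -1.90 (SE 0.62, adjusted p = 0.0267). It was also lower for hoxa2b, by -1.43 (SE 0.40, adjusted p = 0.0118), mafba, by -0.90 (SE 0.21, adjusted p = 0.00345), and egr1, by -0.71 (SE 0.25, adjusted p = 0.0394). AW342687 responded more to DCA, by 1.88 (SE 0.51, adjusted p = 0.00846). Between DCP and PCP, phenols with 2 and 5 chlorines, AW342687 differed by 3.81 (SE 0.54, adjusted p = 0.00249) and no named gene passed. The difference was 1.45 for hoxa2b (95% interval 0.58 to 2.33, adjusted p = 0.0545) and 0.76 for mafba (95% interval 0.30 to 1.21, adjusted p = 0.0546). Between DCA and PCP, AW342687 differed by 5.69 (SE 0.51, adjusted p = 3.44e-07) and no named gene passed, with dlx4a at -1.96 (95% interval -4.10 to 0.18) and mafba at -0.15 (95% interval -0.58 to 0.29). These differences include differences among the controls. In the fit DCA controls lay above DCP controls by 3.57 for dlx4a, 2.38 for rbp4, 1.63 for nkx2.1, 0.81 for hoxa2b, 0.69 for mstnb, 0.56 for mafba and 0.23 for egr1, and each of these genes differed among the 4 control groups (adjusted p from 0.00747 to 0.0480). The channel means of egr1 went the other way, 10.51 in DCA and 11.09 in DCP controls. AW342687 also differed there (adjusted p = 0.000661), with channel means of 8.62 in DCA, 6.25 in DCP, 8.05 in PCP and 6.95 in CdCl2 controls.

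Across probes, 3883 differed between DCA and DCP, 528 between DCP and PCP and 2, AW342687 and AI883170, between DCA and PCP, with 5749, 3344 and 2031 at an unadjusted p under 0.05. The 2 became 1 with scan day as a batch, and within the scan day that held both toxicants 0 passed (1167 at an unadjusted p under 0.05), with 1 DCA high and 1 DCA control channel and 2 residual degrees of freedom. The 528 became 7 with scan day as a batch, 3 with array weights and 1 to 1389 without 1 array, with 14 arrays moving it by over 1.5 times. Over all 4 toxicants the response to the high concentration differed for 5307 probes by limma's F test, with adjusted p = 0.00114 for dlx4a, 0.00222 for rbp4 and 5.76e-06 for AW342687. The response to the low concentration differed for 1 probe, AW342687 (adjusted p = 1.94e-07), with 1186 at an unadjusted p under 0.05.

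The responses to the 2 concentrations of a toxicant share their controls, so their fold changes correlate without any effect. Across the 16406 probes, which are not independent replicates, r was 0.409 for DCA, 0.582 for DCP, 0.521 for PCP and 0.659 for CdCl2, where simulated data with no effect gave 0.50. The covariance was 0.215, 0.333, 0.146 and 0.428, against 0.18 simulated. With the control channels split between the concentrations, the mean r over 10 splits was 0.049, -0.112, 0.115 and 0.070. Single splits ran from -0.247 (DCP) to 0.26 (PCP). The values to set these against are the r with shared controls in that same calculation, 0.509, 0.498, 0.622 and 0.61, not those of the fit. For CdCl2, 89 probes rose and 131 fell at both concentrations, where independent lists would share 13 and 17.7, numbers that leave out the shared controls.

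Unexposed embryos of the 4 exposure days also differed. Of the 47 named genes, 15 differed among the control groups, and the largest ranges were those of dlx4a at 4.55 on the log2 scale (adjusted p = 0.00747), dlx5a at 4.29 (adjusted p = 0.001), rbp4 at 3.36 (adjusted p = 0.0143), nkx2.1 at 2.72 (adjusted p = 0.0143) and mstnb at 2.62 (adjusted p = 0.0480). In the fit, all 5 were highest in DCA controls and lowest in CdCl2 controls, although by channel means rbp4 and nkx2.1 were lowest in DCP controls (10.48 and 10.51). In channel means, rbp4 was at 12.80 ± 0.87 (SD, n = 6) in DCA controls and 10.72 ± 0.95 (SD, n = 6) in CdCl2 controls, and dlx4a at 9.69 ± 0.72 (SD, n = 6) and 7.37 ± 0.92 (SD, n = 6). In all, 4693 probes differed, 972 with scan day as a batch and 2788 without the array of CdCl2 control replicate 6 and PCP control replicate 7. Exposure day and toxicant cannot be told apart in these groups.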

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

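The tests of print block and plate, of a difference among unexposed embryos, of dye bias and of a single array were chosen only after the results were seen. In 10 of 67 groups of 6 channels, an extreme channel lay farther from its nearest neighbour, relative to the range, than Dixon's 95% critical value, which chance gives in about 1 group of 20. On the log2 scale, in DCA high the highest channel of rbp4 was at 13.13 (next 11.20) and that of nkx2.1 at 12.64 (next 10.50), and the lowest of mafba at 9.83 (next 11.12). The lowest of mafba in DCA low was at 10.16 (next 11.29), and that of AW567244 in DCA controls at 0.891 (next 5.61). The highest of AW342687 in DCP low was at 10.44 (next 9.28), and the lowest of BG305996 in DCP high at 4.26 (next 7.94). The lowest of BI892352 in PCP controls was at 12.93 (next 13.95), and in CdCl2 controls dlx4a had its lowest at 5.65 (next 7.25) and tlx2 at 7.38 (next 9.31).

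The response to the high concentration differed among the 4 toxicants, by limma's F test of the difference, for 22 of 22 genes and probes tested. Among named genes the adjusted p was 0.00335 for dlx1a, 0.00114 for dlx4a, 0.00222 for rbp4, 0.00483 for mstnb, 0.00369 for nkx2.1, 0.000658 for mafba, 0.0044 for egr1, 0.00485 for dlx5a, 0.000485 for hoxa2b, 0.011 for hesx1 and 0.000688 for tlx2. Among unnamed probes it was 5.76e-06 for AW342687, 0.00165 for AW567244, 5.92e-05 for BI865553, 0.000204 for BI845755, 0.00584 for AW165158, 0.000261 for BG305996, 0.000373 for BM026584, 0.00042 for BI892352, 0.000873 for BF717383, 0.0388 for BI880958 and 0.0248 for BI880613. All were picked for passing in a comparison, so the share of 22 of 22 is no estimate for other probes.

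A sequence printed in 172 spots (AF025305, left out of the counts above) also moved: by -1.20 (SE 0.26, adjusted p = 0.00425) in DCA high, lower in 165 spots, and by 1.15 (SE 0.26, adjusted p = 0.00232) in CdCl2 high, higher in 161 spots.

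Responses to the high concentrations of DCA and CdCl2 ran opposite ways: across probes r was -0.466, where simulated data with no effect gave 0.029, and of 1977 probes past the threshold in both, 897 rose with DCA and fell with CdCl2 and 1078 did the reverse. Noise shared through linking arrays is argued against by r = -0.372 with each response fitted on its own 6 arrays, scan day by r = -0.403 with scan day as a term, and print block or plate by r = -0.464 after their medians were removed. An axis along which unexposed embryos of different days also differ may underlie it: the DCA response correlated at 0.292 with the difference of the CdCl2 and PCP controls (0.0344 simulated; 0.439 over probes present on at least 18 arrays), short of the 0.3 set for it over all probes. The CdCl2 response correlated at 0.0852 with the difference of the DCA and PCP controls and at 0.52 with that of the DCA and DCP controls, and the PCP and DCP responses at 0.208 and -0.14 with that of the CdCl2 and DCA controls. That explanation and an effect of the toxicants cannot be told apart, because each toxicant had its own exposure day.

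AW342687 was the leading probe after both DCA and DCP. A fault of the slide around the spot is argued against by its 8 neighbouring spots, whose median log2 fold change in DCA high was -0.04 (-1.28 to 1.22). Its calls after DCP were lost in 3 (low) and 2 (high) of 15 alternatives, and it also differed among the control groups (adjusted p = 0.000661). Dye bias is argued against by the smaller ratio of the arrays of opposite orientation, 6.06 on the log2 scale. Cross-hybridisation of other transcripts to the probe was not tested, so a response of its transcript to these compounds remains a hypothesis that these values suggest.

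With scan day as a batch, the 4194 probes of CdCl2 high against control became 722, of which 715 were among the 4194. Lower precision of that fit may be a part of the loss. The slope of its log2 fold changes on the others was 0.933 over all probes and 0.896 over the 4194. The median SE rose from 0.342 to 0.402, with 17 residual degrees of freedom. The count of DCA high, however, hardly moved in the same fit. The median absolute log2 fold change of the 4194 went from 0.996 to 0.883 and 100% kept their sign, so part of the change in size stays open as an effect of scan day. A single array as the whole cause is argued against by the lowest count with 1 array left out, 1765.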

How the results depend on the processing

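Alternatives with an offset of 50, without class E spots (the lowest confidence class), without the array of CdCl2 control replicate 6 and PCP control replicate 7, and without 5 arrays of low weight were chosen after seeing the data. For single genes and probes, the alternatives covered 36 log2 fold changes past the threshold, of named genes and of unnamed probes with the largest changes. AW342687 in CdCl2 high, the differences between compounds for single genes and values that did not pass were not among them. None of the 36 reversed under any alternative run, but the larger share of calls turned to the other direction in some counts. This was so for DCP high and CdCl2 high with scan day as a batch and for DCP high and DCP minus PCP without 5 arrays (shares given with those counts), for CdCl2 high without class E spots (49.4% higher against 52.3%), for DCA minus DCP with the block and without class E spots (50.8% and 50.9% against 48.7%), and in counts of 1. Counts are of probes past the threshold, main values in brackets, and the cause was not tested except where fewer arrays or probes enter by construction. Print-tip loess moved DCP high against low to 2 (1). The deposited table gave 1770 for DCA high (2918), 1509 for DCA high against low (2622; 33.7% higher against 43.9%), 0 for DCP high (44), 2 for DCP high against low, 1 for PCP low (0), 1 for PCP high against low (0), 0 for CdCl2 low (242), 1565 for CdCl2 high (4194), 2169 for DCA minus DCP (3883), 0 for DCP minus PCP (528), 2781 for the 4 control groups (4693), 3335 for the high response of 4 toxicants (5307) and 2 for the low response (1), and an r of 0.442 between CdCl2 low and high (0.659). The dim probe filter gave 2 for DCP high against low, 523 for CdCl2 low and 840 for DCP minus PCP. Without a dye term DCP high had 29 and CdCl2 low 0. Array weights gave 1 for DCP low (14), 2 for DCP high, 0 for DCP high against low, 1722 for CdCl2 low, 1904 for CdCl2 high against low (0), 3 for DCP minus PCP and 6 for DCA minus PCP (2). A trended robust prior gave 659 for CdCl2 low, 861 for DCP minus PCP and 4 for DCA minus PCP. Scan day as a batch gave 17 for DCP high (58.8% higher against 36.4%), 0 for DCP high against low, 1 for PCP high (2), 0 for CdCl2 low, 722 for CdCl2 high (40% higher against 52.3%), 7 for DCP minus PCP, 1 for DCA minus PCP and 972 for the 4 control groups. Separate channels gave 7 for DCA low (2), 33 for DCP low, 16 for DCP high against low, 159 for CdCl2 low (18.2% higher against 40.1%), 344 for DCP minus PCP and 2 for the low response of 4 toxicants. With the replicate number as a block on separate channels the counts were 1 for DCA low, 1635 for DCA high, 25 for DCP low, 163 for DCP high, 110 for DCP high against low, 1 for PCP low, 265 for PCP high (71.7% higher against 50%), 56 for CdCl2 high against low, 1925 for DCA minus DCP, 1 for DCA minus PCP and 2 for the low response. The numbers were not taken to pair the samples, since that needed every pair of the same number to correlate over 0.1. Of 50 such pairs 28 did (mean r of deviations 0.105), and of 358 others 55 did (mean r -0.0278). The rule is strict, and pairs of the same number correlated more on average. A pairing of some samples is thus not excluded, and the main fit leaves it out. That block could not be used for the 4 control groups. Without the 2 arrays of the repeated PCP control number PCP high had 0. An offset of 50 gave 1 for DCP low, 2 for DCP high, 0 for DCP high against low, 557 for CdCl2 low and 1 for DCA minus PCP. Without class E spots the counts were 1 for DCA low, 215 for DCP high, 4 for PCP low, 3 for PCP high against low, 986 for CdCl2 low, 1189 for DCP minus PCP, 5 for DCA minus PCP and 4 for the low response, and r between DCP low and high was 0.787 (0.582). Without the array that stood apart they were 1 for PCP high, 0 for CdCl2 low and 2788 for the 4 control groups. Without 5 arrays of low weight they were 1330 for DCA high, 25 for DCP high (88% higher against 36.4%), 0 for DCP high against low, 1 for PCP high, 2395 for DCA minus DCP, 17 for DCP minus PCP (82.4% higher against 32.2%), 1 for DCA minus PCP and 2195 for the 4 control groups. The 6 arrays of a toxicant alone gave 1 for DCA low, 1 for DCA high, 0 for DCA high against low, 0 for DCP low, 0 for DCP high, 0 for DCP high against low, 0 for PCP high, 0 for CdCl2 low and 0 for CdCl2 high, in a fit of fewer arrays. With each array left out in turn the range was 1 to 4 for DCA low, 1346 to 3197 for DCA high, 942 to 3131 for DCA high against low, 3 to 85 for DCP low, 8 to 714 for DCP high, 0 to 7 for DCP high against low, 0 to 1 for PCP low, 0 to 3 for PCP high, 0 to 880 for CdCl2 low, 1765 to 4478 for CdCl2 high, 0 to 3 for CdCl2 high against low, 1 to 1389 for DCP minus PCP, 1 to 4 for DCA minus PCP, 2788 to 4937 for the 4 control groups and 1 to 5 for the low response. The 3 of CdCl2 high against low came without the array of DCP high replicate 8 and CdCl2 high replicate 8. Of the 36 log2 fold changes covered, 34 no longer passed with the 6 arrays alone, 24 with the deposited table and 17 with scan day, all in the same direction. AW342687 passed in DCA low and high under 15 of 15 alternatives, in DCP low under 12 and in DCP high under 13. List tests stayed at 0 past the threshold with an estimated correlation and with the block. The comparisons of background corrections and of excluded spots were not run, because no background column is given and 0 spots were excluded. Signal over background limits dim probes: empty spots were present in 7.79% of channels.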

Other observations

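The groups of named genes and the 13-probe set were made after the data were opened, and which of their results to describe was decided after they were seen; the splits were planned. Of 64 tests of 8 sets, 1 passed with the preset correlation and 0 with an estimated one. In DCP low, 41 of the 47 named genes lay above 0 (median 0.34) and none passed. In CdCl2 high 32 lay above 0 and in DCA high 15. The named genes with a call carry probe numbers of the same source plate. A shift that they share may thus come from the plate, which was not tested for these genes. For retinoid genes, rbp4 was the 1 of 3 that fell after DCA high (median -0.86) and that rose after CdCl2 high (median 0.03). For growth factor genes, mstnb was the 1 of 5 that fell after DCA high (median -0.61) and that rose after CdCl2 high (median 0.36). Of 7 Hox genes none passed after DCA high (median -0.22). None of the 3 cytochrome P450 genes or the 2 translation genes passed in either. Of the 13 probes that share the accession of 1 RefSeq molecule, 2 rose after DCA high (median 0.23, camera adjusted p = 0.317) and 3 fell after CdCl2 high, 8 when adjusted over the list alone (median -0.36, camera adjusted p = 0.063). Correlations between toxicants were stronger in brighter probes, whether negative or positive. From mean log2 intensities under 6 to those over 12, r went from -0.016 to -0.868 between DCA high and CdCl2 high, from 0.2 to 0.594 between DCA high and PCP high, and from 0.156 to 0.691 between DCP high and CdCl2 high. Over all probes the latter pairs had r of 0.349 and 0.357, against 0.13 simulated for each.

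The counts were set against 100 splits of the same channels into groups of the same sizes, the real one included. The real split had the highest count for DCA high against control (2918, highest other 2187), DCA high against low (2622, 744) and CdCl2 high against control (4194, 2640). It was also the highest for the 4 control groups (4693, 2041), the high response of 4 toxicants (5307, 1785) and DCA minus DCP (3883, 926). Chance is argued against there but not excluded, as 1 of 100 is the smallest share possible and many such tests were run. With 1 array left out, DCA high fell to 1346 and CdCl2 high to 1765, each below its highest other split. The real split was likewise the highest for CdCl2 low (242, 2) and DCP minus PCP (528, 142). However, 31 and 14 arrays each move these counts by over 1.5 times, down to 0 and 1, so chance is argued against less firmly there. For DCA minus PCP, 4 of 100 splits called at least the real 2, with a highest of 1673. As 1 of many such tests, and with 12 arrays that each move that count by over 1.5 times, this argues against chance only weakly. For the counts alone, chance cannot be excluded for DCA low (2, reached by 5 splits, highest other 4), DCP low (14, by 8, 53), DCP high against control (44, by 27, 399), DCP high against low (1, by 65, 193), PCP high against control (2, by 7, 4) or the low response of 4 toxicants (1, by 14, 2). A count of so few probes does not speak against AW342687 itself, whose adjusted p was 2.34e-11 in DCA low and 1.94e-07 for the low response. Where the real count was 0, all 100 splits reach it by construction and the splits decide nothing; the highest other was 25 for PCP low, 8 for PCP high against low and 631 for CdCl2 high against low. Some splits called several times the real count, as for DCP high and DCA minus PCP, and the reason was not tested. Structure of the samples besides the groups is possible. For DCA minus PCP the labels were mixed within each toxicant, so a split can also keep part of the real DCA grouping.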
